A study of Mus musculus with 28 samples.

How the data were processed

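The series measured RNA of mouse hippocampus on Affymetrix Mouse Gene 1.0 ST arrays, 28 in all, from 100 ng of total RNA each. Per the labels, 18 arrays are from mice of 10 weeks and 10 from aged mice of 64.7 to 71 weeks. The submitters' processing notes name Affymetrix Expression Console, with no version; the normalization algorithm was not given in the sources used here. The deposited values are log2 signals, 1 column per array, for 35557 probe sets. The 28 columns were used, and there were 0 other columns of per-sample values. No raw intensities were analysed here.

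Groups follow titles and treatment labels. The labels conflict in 3 places: a source name of the fosB d/d saline arrays speaks of kainate while title and treatment say saline, so they were grouped as saline; a protocol gives 14 months for all mice while the age labels give 10 weeks for the young; and all mice are labelled female while the young arrays carry Y-linked signal. Replicates of a group correlated at 0.978 to 0.996.

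Of the 35557 probe sets 23410 are in the gene table, 21789 with 1 symbol, 1621 with several and 12147 with none. Probe sets with 1 symbol were kept, and the probe set with the highest mean stood for each of the 999 genes with more than 1, leaving 19938 genes. Names were checked by Entrez identifier against the RefSeq gene table of GRCm38.p6, which matched 21698 probe sets and changed 0 symbols. That table served for names and for the order and distance of genes around Fosb; no coordinate was used otherwise.

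Each comparison was a contrast of group means in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation and no replicate block. The 18 young arrays formed 1 fit and the 10 aged arrays another, and aged against young wild type used all 28 arrays. P values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene passed at an adjusted p under 0.05. Where the median gene moved by more than 0.1 log2 units, changes are also given minus that median. The SE and adjusted p beside such a change are those of the change as deposited. The change minus the median was not tested itself. Differences of the KA response between genotypes were interaction contrasts. Adjusted p values in the report are from limma, or from its camera function for lists.

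Gene lists were fixed before the data were examined, as were the groups, the main design and the first set of alternatives. In all, 42 lists with at least 5 measured genes were tested by camera with a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. Within a list, members were also counted after adjusting p over the list alone. The naming rule took Fosb, and per direction the 8 passing genes with the largest change, leaving out predicted loci, small RNAs, receptor genes of smell and the vomeronasal organ, and immunoglobulin segments. Where fewer than 3 genes passed it took the 3 of smallest p. For each called list it took the 4 members of smallest p in the direction of the call, and other members of fixed lists were allowed with their values. Vmn1r180, Zfp180, Kptn and Pnmal2 near Fosb and the sex-linked genes in single arrays were named after their values were seen.

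Genes near Fosb were those within 10 Mb, compared with other genes by Fisher's exact test. A score took the genes called for KA in 1 mutant and compared the other mutant with wild type after KA by an exact permutation test. Saline values were not subtracted. Splits of the same arrays were counted for 10 groupings of 3 against 3 and 100 relabellings for the interactions.

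Replicate numbers recur in the groups, with no stated meaning. Deviations of same-numbered arrays from their group means were correlated before the fits were compared. With 3 pairs, the numbers paired the arrays (all above 0.1) in fosB d/d against wild type saline, 0.41 to 0.78, and in fosB-null against fosB d/d saline, 0.22 to 0.31. They paired them as well in fosB-null against wild type KA, 0.35 to 0.42, in aged fosB-null with epilepsy against wild type, 0.20 to 0.47, and in KA against saline in fosB d/d, 0.29 to 0.34, and in fosB-null, 0.18 to 0.37.

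Alternatives on all comparisons were quantile normalization, the replicate block, the dimmest 30 percent of genes left out, the mean of probe sets, trended and robust moderation, fits of only the compared groups, all 28 arrays in 1 fit, array weights, and each array left out. Age was a covariate in the aged mice. Genes near Fosb were also taken at 2 and 30 Mb, and the score from 100 genes per direction or from quantile-normalized values. Quantile normalization with the array set or replicate number as a block, fits within 1 array set and the unadjusted threshold near Fosb were added after the data were seen. The closing section gives their effect.

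The procedure was tested on simulated data of 19938 genes with 200 changed. With the offsets of these arrays, a change of 1 log2 unit was recovered in 89.6 percent of genes for KA in wild type and in 56.7 percent for the interaction in fosB-null mice. A change of 0.5 was recovered in 13.4 and 2.99 percent. Of 40 random lists 0 were called, but genes were drawn independently there, so false calls of lists of correlated genes were not tested. Unchanged genes called numbered 2 for KA in wild type, 26 for fosB-null against wild type after KA and 8 for the interaction. Each simulated offset was the same for every gene of an array. False calls of genes from gene-specific differences between array sets were therefore not tested either. Values that would need a genome sequence were not analysed here.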

Results

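The series holds 28 arrays of mouse hippocampus, 18 from mice of 10 weeks and 10 from aged mice. The young mice were wild type, fosB-null (G/G) or fosB d/d, which lacks the FosB protein, and had received saline or kainate (KA), with 3 arrays per group. The aged mice were wild type (3 arrays), fosB-null with epilepsy (3), fosB-null without epilepsy (2) and fosB d/d (2). The replicates are labelled biological, so the animals are presumably separate, and the small number of arrays per group limits the precision of every value. The time between KA and sampling was not given in the sources used here.

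The deposited arrays differ in level. The median log2 value ran from 7.95 to 8.43 over the 28 arrays, and the young arrays were parted into 3 sets after the data were seen. Medians were 8.07 to 8.11 in set 1, 8.33 to 8.43 in set 2 and 8.05 to 8.11 in set 3. Level thus parts set 2 alone. Set 1 is replicate 1 of the 6 young groups and was taken by its number. When arrays were clustered on the probe sets outside the gene table, these 6 fell together, with 0 other young arrays and 1 aged array. Set 2 holds replicates 2 and 3 of the saline groups and of wild type KA, and set 3 holds replicates 2 and 3 of fosB-null KA and fosB d/d KA, so set 3 holds no wild type and no saline array. For this reason changes that carry a shift of the median gene are given relative to that shift, and counts after quantile normalization stand beside the counts on the deposited scale. The SE and adjusted p beside a relative change belong to the change as deposited. Counts of list members, also those adjusted over the list alone, are on the deposited scale unless stated otherwise, so they include the shift.

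**Figure D1:**
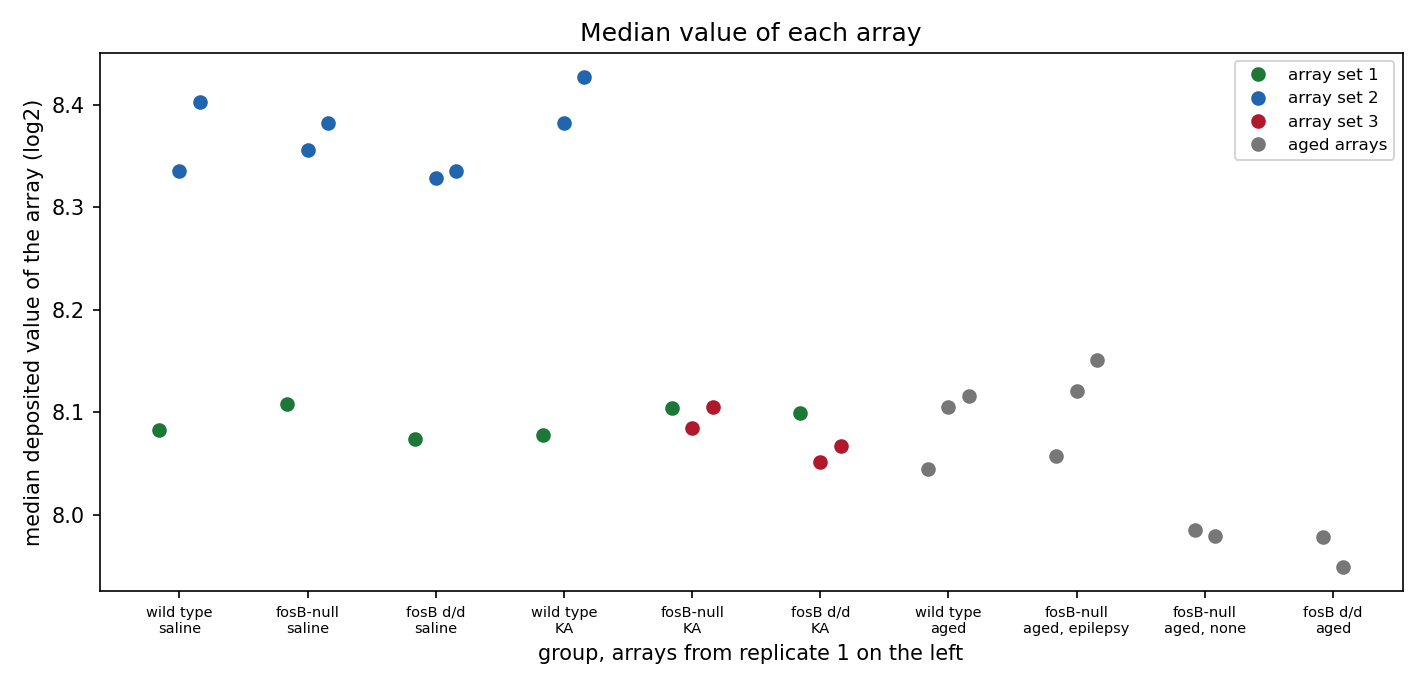
Median deposited log2 value of each of the 28 arrays, by group, coloured by array set (aged arrays in grey). Medians ran from 7.95 to 8.43, and each point is 1 array.

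Fosb, the targeted gene, was at 8.87 ± 0.23 (mean ± SD of log2 values) in wild type saline, 8.68 ± 0.38 in wild type KA, 8.56 ± 0.13 in fosB-null saline and 8.15 ± 0.32 in fosB-null KA. It was at 9.26 ± 0.38 in fosB d/d saline and 8.92 ± 0.11 in fosB d/d KA, with 3 arrays each. In the aged mice it was at 9.66 ± 0.26 in wild type, 8.84 ± 0.72 in fosB-null with epilepsy, 8.65 ± 0.15 in fosB-null without epilepsy and 9.80 ± 0.01 in fosB d/d. Fosb passed in no comparison on the deposited scale: the difference of fosB-null from fosB d/d was -0.69 in saline (standard error, SE, 0.21, limma adjusted p = 0.958). Which part of the transcript the Fosb probes cover was not given in the sources used here, so its level does not settle the genotype labels.

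In wild type mice KA raised 20 of 31 reactive astrocyte genes, 9 of 25 cytokines and chemokines and 7 of 27 late activity genes, and lowered 4 of 20 astrocyte markers (3 arrays per group). Timp1, an inhibitor of matrix metalloproteinases, rose by 3.88 log2 units (SE 0.32, adjusted p = 5.6e-06). Hspb1, a small heat shock protein, rose by 2.58 (SE 0.28) and Gldn, a protein of nodes of Ranvier, by 2.40 (SE 0.24). Ccl12, a monocyte chemokine, rose by 2.23 (SE 0.28) and Trh, the precursor of thyrotropin-releasing hormone, by 2.25 (SE 0.40). Among lower genes, Tdo2, a tryptophan-degrading enzyme found in dentate granule cells, changed by -1.64 (SE 0.23) and Etnppl, an astrocyte enzyme, by -1.59 (SE 0.17).

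The reactive astrocyte list changed most: 20 of 31 measured members rose and 0 fell. Adjusted over the list alone, 23 rose, and the list median stood 1.11 above that of all genes (camera adjusted p = 1.9e-37; adjusted p = 0.0538 with an estimated correlation). Gfap, the astrocyte intermediate filament, rose by 1.51 (SE 0.14), Serpina3n, a protease inhibitor, by 1.81 (SE 0.15), and S1pr3, a sphingosine phosphate receptor, by 2.07 (SE 0.22). Markers of resting astrocytes moved the other way: 4 of 20 fell and 0 rose (adjusted over the list alone, 10 fell and 3 rose), with Gja1, the gap junction protein, at -1.02 (SE 0.13) and Mfge8 at -0.81 (SE 0.15). That list was called down (adjusted p = 1.9e-05; adjusted p = 0.542 with an estimated correlation).

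Inflammatory lists were called up. Of 25 cytokines and chemokines 9 rose (adjusted over the list alone, 12 rose and 1 fell), among them Cxcl10, an interferon-induced chemokine, by 2.01 (SE 0.34) and Lif, a cytokine of the interleukin 6 family, by 1.34 (SE 0.16). The test of this list gave adjusted p = 2.4e-10 (adjusted p = 0.191 with an estimated correlation). Of 23 interferon response genes 8 rose (13 adjusted over the list alone), such as Ifitm3 by 1.16 (SE 0.18) and Usp18 by 1.05 (SE 0.17), with adjusted p = 9.5e-12 (adjusted p = 0.415 with an estimated correlation). Of 19 genes of activated microglia 8 rose (adjusted over the list alone, 10 rose and 1 fell), with Gpnmb at 1.06 (SE 0.11) and Cst7, a cystatin, at 1.06 (SE 0.14); adjusted p was 2.1e-09 (adjusted p = 0.248 with an estimated correlation). Of 23 microglia markers 5 rose (adjusted over the list alone, 12 rose and 1 fell), with Ly86 at 1.26 (SE 0.16); adjusted p was 4.4e-06 (adjusted p = 0.533 with an estimated correlation). Of 18 complement and MHC genes 2 rose, C4b by 0.99 (SE 0.18) and C1qc by 0.46 (SE 0.11); 6 rose adjusted over the list alone, with adjusted p = 1.0e-04 (adjusted p = 0.542 with an estimated correlation).

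Genes regulated late after neuronal activity rose: 7 of 27 (9 adjusted over the list alone), with Nptx2, a neuronal pentraxin, at 1.24 (SE 0.11) and Bdnf, a neurotrophin, at 0.60 (SE 0.11). That list gave adjusted p = 2.1e-05 (adjusted p = 0.533 with an estimated correlation). Of 24 neuropeptide genes 5 rose (adjusted over the list alone, 8 rose and 2 fell): Gal, the galanin precursor, was at 1.87 (SE 0.11, adjusted p = 5.9e-08), Penk, the enkephalin precursor, at 0.91 (SE 0.17), and Npy at 0.76 (SE 0.15). The test of the list gave adjusted p = 0.00305 (adjusted p = 0.542 with an estimated correlation). In the Fos and Jun family 1 of 7 rose (2 adjusted over the list alone), Fosl1 by 1.18 (SE 0.19), with adjusted p = 0.0112 (adjusted p = 0.545 with an estimated correlation). The immediate early list, 32 genes of which 4 rose (5 adjusted over the list alone), was not called (adjusted p = 0.298): its median lay below that of all genes (-0.04) while its mean was above 0. Fos was at 0.55 (SE 0.16, adjusted p = 0.0962) and Arc at -0.24 (adjusted p = 0.703).

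Of 26 genes of matrix remodelling 6 rose and 1 fell (adjusted over the list alone, 7 rose and 1 fell), with Cd44, a hyaluronan receptor, at 2.13 (SE 0.25) and Tnc, tenascin C, at 0.82 (SE 0.14); adjusted p was 3.3e-05 (adjusted p = 0.542 with an estimated correlation). Dentate granule cell markers were called down, with 3 of 16 lower and 1 higher (adjusted over the list alone, 6 and 1); beside Tdo2, Trpc6, a cation channel, changed by -0.57 (SE 0.14). Adjusted p for that list was 5.0e-06 (adjusted p = 0.533 with an estimated correlation). Of 20 myelin genes 2 fell, Aspa (-0.77, SE 0.14) and Cnp (-0.57, SE 0.12); adjusted over the list alone, 3 fell and 1 rose, with adjusted p = 1.6e-04 (adjusted p = 0.542 with an estimated correlation). Of 51 potassium and HCN channel genes 2 fell, Kcnk4 (-0.54, SE 0.12) and Kcnb2 (-0.50, SE 0.13), and of 23 glutamate receptor genes 1 fell, Grin2c (-0.50, SE 0.12); adjusted over the list alone, the counts were again 2 and 1. These 2 lists gave adjusted p = 7.7e-06 and 1.9e-04 (adjusted p = 0.545 and 0.542 with an estimated correlation). Choroid plexus markers stood 0.80 above the median of all genes although 0 of 17 passed (adjusted p = 1.9e-04; adjusted p = 0.545 with an estimated correlation). Adjusted over the list alone, 0 of these markers passed in any comparison of young mice on the deposited scale.

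In this comparison limma called 323 genes higher and 187 lower of 19938, and 687 higher and 740 lower after quantile normalization, with 486 of the 510 genes kept. Leaving out replicate 2 of wild type saline left 255 genes; with quantile normalization the count was 3634 with the array set block and 3632 within set 2. Of 42 lists 14 were called up and 15 down, and 0 were called with an estimated correlation. Within set 2 after quantile normalization the calls of neuropeptides (adjusted p = 0.0527), potassium and HCN channels (adjusted p = 0.0527), glutamate receptors (adjusted p = 0.067) and choroid plexus (adjusted p = 0.272) were lost. There the immediate early list was called up (adjusted p = 0.0459).

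In fosB-null mice KA raised 4 of 31 reactive astrocyte genes as deposited, a count that includes the shift of the median gene. Relative to the median gene, which moved by -0.17, Timp1 rose by 2.96 (SE 0.32, adjusted p = 8.4e-04), Serpina3n by 1.45 (SE 0.15), Gfap by 1.40 (SE 0.14) and Slc14a1, a urea transporter, by 1.25 (SE 0.15). Lower genes were Rasd2 (-0.84, SE 0.16), Thbs4, a thrombospondin (-0.65, SE 0.13), and Arntl, a clock transcription factor (-0.60, SE 0.12). Adjusted over the list alone, 14 reactive astrocyte genes rose, and the list had its median 0.50 above all genes (adjusted p = 5.2e-49; adjusted p = 0.0187 with an estimated correlation).

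Genes of cholesterol synthesis were called up in fosB-null mice with a median 0.42 above all genes (adjusted p = 2.2e-20; adjusted p = 0.0751 with an estimated correlation). Of 18 measured genes 0 passed among all genes, and 1 rose adjusted over the list alone; Sqle, squalene epoxidase, was at 0.69 (SE 0.15) and Idi1, an isomerase of the pathway, at 0.57 (SE 0.17) relative to the median gene. The interferon list had 0 of 23 passing, also adjusted over the list alone, with Ifit3 at 1.02 (SE 0.30) and a median 0.21 above all genes (adjusted p = 2.2e-07; adjusted p = 0.939 with an estimated correlation). Activated microglia genes had 0 of 19 passing and 3 higher adjusted over the list alone, with Cd63 at 0.98 (SE 0.16, adjusted p = 0.0738); the list was called up (adjusted p = 2.2e-07; adjusted p = 0.468 with an estimated correlation), its median as deposited being -0.01 and its mean 0.05. Markers of choroid plexus lay 0.41 above all genes with 0 of 17 passing (adjusted p = 1.0e-07; adjusted p = 0.939 with an estimated correlation), and this call was lost after quantile normalization (adjusted p = 0.0945). In limma 7 genes were higher and 8 lower, and 91 and 48 after quantile normalization, with all 15 kept. With the replicate number as a block the count was 134, and without replicate 1 of fosB-null KA it was 119, without replicate 3 of fosB-null saline 3. With quantile normalization and the array set as a block, 6 of the 15 were kept, Timp1 (adjusted p = 0.0311), Gfap (0.0265) and Serpina3n (0.0265) among them.

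In fosB d/d mice KA raised Timp1 by 2.08 relative to the median gene (which moved by -0.17; SE 0.32, adjusted p = 0.0441), Gfap by 1.31 (SE 0.14, adjusted p = 0.00155) and Slc14a1 by 1.17 (SE 0.15). Thbs4 (-0.96, SE 0.13), Rskr (-0.95, SE 0.17) and Psrc1 (-0.50, SE 0.11) were lower. The reactive astrocyte list had 2 of 31 higher (10 adjusted over the list alone) and a median 0.39 above all genes (adjusted p = 2.5e-33; adjusted p = 0.0574 with an estimated correlation). Cholesterol synthesis had 0 of 18 passing (2 higher adjusted over the list alone) and a median 0.40 above all genes (adjusted p = 4.6e-22; adjusted p = 0.0574 with an estimated correlation). The interferon list had 0 of 23 passing (3 higher adjusted over the list alone) and a median 0.25 above all genes (adjusted p = 2.9e-13; adjusted p = 0.437 with an estimated correlation). The late activity list was called up with 0 of 27 passing, also adjusted over the list alone (adjusted p = 9.3e-06; adjusted p = 0.68 with an estimated correlation), although its median as deposited was -0.05 and stood 0.12 above that of all genes. In limma 3 genes were higher and 3 lower, and 48 and 37 after quantile normalization, with all 6 kept. The count was 475 with the replicate number as a block, 118 without replicate 1 of fosB d/d KA and 2 without replicate 2 of fosB d/d saline. With quantile normalization and the array set as a block the count was 36, and Timp1 was lost with a larger SE (1.91, SE 0.42, adjusted p = 0.103).

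The response to KA differed from wild type in a few genes, tested as the interaction of genotype and treatment. In fosB-null mice the response of Gal differed by -1.70 relative to the median gene (SE 0.16, adjusted p = 1.6e-05), that of Thbs4 by -1.23 (SE 0.18, adjusted p = 0.00193) and that of Nptx2 by -1.22 (SE 0.16, adjusted p = 5.6e-04). Gal was at 8.81 to 9.01 in the wild type KA arrays against 6.80 to 7.21 in saline, and at 7.30 to 7.44 in the fosB-null KA arrays against 7.31 to 7.42 in saline. In fosB d/d mice 3 genes were called, Thbs4 at -1.54 (SE 0.18, adjusted p = 4.5e-04), Gal at -1.07 (SE 0.16, adjusted p = 0.00358) and Nptx2 at -1.01 (SE 0.16, adjusted p = 0.0038). Thbs4 went from 9.37 to 9.95 in wild type, from 9.47 to 8.64 in fosB-null and from 9.67 to 8.54 in fosB d/d mice. Negative differences in fosB-null mice were also called for Klk1b8 (-1.20), Bcl2a1c (-1.13), Pate13 (-1.14) and Cst7 (-0.96). A positive one was called for Vmn1r180, a vomeronasal receptor gene within 10 Mb of Fosb that was lower in fosB-null than in wild type saline mice.

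**Figure D2:**
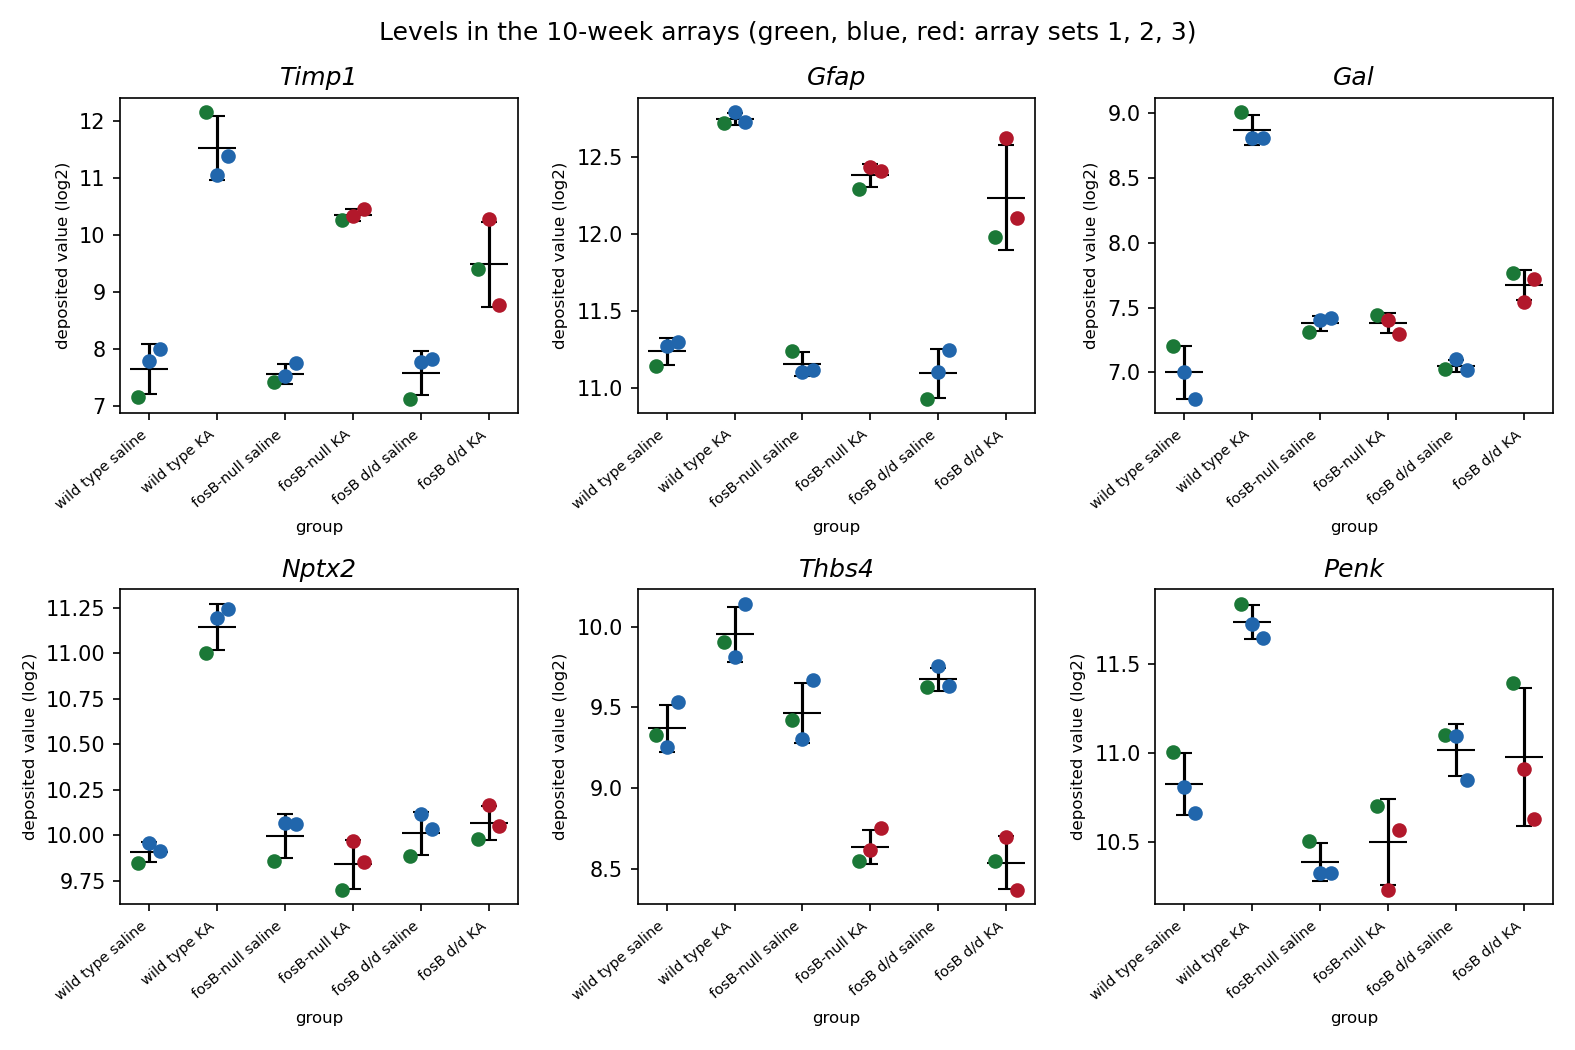
Deposited log2 values of Timp1, Gfap, Gal, Nptx2, Thbs4 and Penk in the 6 young groups, 1 point per array (3 per group), coloured by array set. Bars are mean ± SD; Timp1 went from 7.66 to 11.53 in wild type.

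By lists, the response of reactive astrocyte genes was called down in each mutant. In fosB-null mice 0 of 31 passed and 10 were lower adjusted over the list alone, with a median of -0.39 against all genes (adjusted p = 2.6e-05; adjusted p = 0.697 with an estimated correlation). In fosB d/d mice 0 passed and 19 were lower adjusted over the list alone, with a median of -0.58 against all genes (adjusted p = 1.8e-13; adjusted p = 0.501 with an estimated correlation). Cytokines and chemokines were called down in both, with 0 of 25 passing and 9 lower adjusted over the list alone each time; Lif was at -1.03 (SE 0.23, adjusted p = 0.0571) in fosB-null and -1.01 (SE 0.23, adjusted p = 0.125) in fosB d/d mice. The list tests gave adjusted p = 2.6e-05 and 7.5e-07 (adjusted p = 0.697 and 0.501 with an estimated correlation). Of 24 neuropeptide genes 1, Gal, was lower in each mutant, and 8 adjusted over the list alone, with adjusted p = 0.00957 and 0.00141 (adjusted p = 0.697 and 0.575 with an estimated correlation). Activated microglia genes were called down in fosB d/d mice, with 0 of 19 passing and 11 lower adjusted over the list alone (adjusted p = 9.0e-07; adjusted p = 0.501 with an estimated correlation). Astrocyte markers were called up in fosB-null mice with 0 of 20 passing, also adjusted over the list alone, Gja1 at 0.73 (SE 0.19) among them (adjusted p = 2.6e-05; adjusted p = 0.697 with an estimated correlation). With array weights the calls of reactive astrocyte genes (adjusted p = 0.18 in fosB-null and 0.483 in fosB d/d mice) and neuropeptides (adjusted p = 0.215 and 0.12) were lost. In fosB d/d mice those of cytokines and chemokines (adjusted p = 0.118) and activated microglia (adjusted p = 0.483) were lost as well.

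In limma the difference in response was positive for 1 gene and negative for 7 in fosB-null mice, and for 0 and 3 in fosB d/d mice; after quantile normalization these were 16 and 21, and 0 and 4. Of the called genes 6 of 8 and 2 of 3 were kept; Gal in fosB d/d mice was lost (-0.95, SE 0.21, adjusted p = 0.15), as were Klk1b8 (-0.99, SE 0.28, adjusted p = 0.136) and Cst7 (-0.82, SE 0.20, adjusted p = 0.0992) in fosB-null mice. Without replicate 1 of wild type KA the fosB-null count was 1521, and without replicate 2 of wild type saline 4; without replicate 2 of fosB d/d KA the fosB d/d count was 18. With quantile normalization and the array set as a block the counts were 243 and 160. Among 100 relabellings of genotype within treatment 13 gave at least 8 genes and 9 gave at least 3, but these relabellings mix the array sets, so they do not settle whether chance gives such counts.

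A score of the KA response, computed from the genes called in the other mutant, was 1.24 ± 0.18 in fosB-null KA and 1.38 ± 0.25 in wild type KA (difference -0.14, exact permutation p = 0.6, 3 arrays each). It rests on 3 raised and 3 lowered genes called in fosB d/d mice. The lowered genes include Thbs4, which was higher after KA in wild type mice and so lowers the wild type score. Genes whose response was called in wild type alone do not enter, so the score cannot show a response lost in both mutants. For fosB d/d, with 7 raised and 8 lowered genes called in fosB-null mice, the difference was -0.65 (exact permutation p = 0.2). The smallest p that 3 against 3 arrays allow is 0.1.

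With saline, the gene that passed between fosB-null and wild type mice on the deposited scale was Vmn1r180, which lies within 10 Mb of Fosb. It was lower in fosB-null mice and outside the naming rule, so it was chosen after its value was seen. Acat3, an acetyl-CoA acetyltransferase, was at -0.75 (SE 0.12, adjusted p = 0.0684), the histone gene H2ac4 at -0.92 (SE 0.15, adjusted p = 0.0684) and Ap2s1, a clathrin adaptor subunit, at -0.53 (SE 0.10, adjusted p = 0.12). Cholesterol synthesis genes were called down (median -0.20 against all genes) with 0 of 18 passing, also adjusted over the list alone, Insig1 being at -0.40 (SE 0.15; list adjusted p = 9.1e-06; adjusted p = 0.996 with an estimated correlation). Genes of mitochondrial respiration were called down by a smaller median, -0.10, with 0 of 31 passing, also adjusted over the list alone, Cox4i1 being at -0.32 (SE 0.16; list adjusted p = 5.4e-04; adjusted p = 0.996 with an estimated correlation). That call was lost after quantile normalization (adjusted p = 0.0583) and within set 2 (adjusted p = 0.123). Choroid plexus markers stood 0.49 above all genes with 0 of 17 passing (adjusted p = 0.0018; adjusted p = 0.996 with an estimated correlation). The choroid plexus call was lost with quantile normalization and the array set as a block (adjusted p = 0.0734) and without replicate 2 of wild type saline (adjusted p = 0.944) but kept within set 2 (adjusted p = 0.00838). In limma 0 genes were higher and 1 lower, with 946 at an unadjusted p under 0.05, and 6 and 10 after quantile normalization. With quantile normalization the count was 111 with the replicate block, 319 with the array set block and 1233 within set 2 (2 arrays per group). The count was 0 without replicate 2 and 5 without replicate 1 of wild type saline.

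With saline, fosB d/d mice had no called gene against wild type. Bpifb9b was at -1.26 (SE 0.23, adjusted p = 0.217), Pglyrp1, a peptidoglycan recognition protein, at -0.68 (SE 0.11, adjusted p = 0.217) and Serpinb1a, a protease inhibitor, at -0.54 (SE 0.10, adjusted p = 0.217). Circadian clock genes were called down with 0 of 16 passing and 3 lower adjusted over the list alone, Ciart at -0.85 (SE 0.21) and Dbp at -0.59 (SE 0.20) among the members (adjusted p = 4.9e-08; adjusted p = 0.922 with an estimated correlation). The markers of choroid plexus were 1.13 above all genes, with 0 of 17 passing and Folr1, a folate receptor, at 1.17 (adjusted p = 2.8e-31, and adjusted p = 0.313 with an estimated correlation). The list mean per array, each gene centred over the arrays, was -0.86, -1.12 and 0.96 in wild type saline. In fosB d/d saline it was 0.60, 1.02 and 0.64, so replicate 3 of wild type lay within the range of the mutant arrays. Ependyma markers stood 0.24 above all genes, with 0 of 15 passing, also adjusted over the list alone (adjusted p = 4.9e-08; adjusted p = 0.922 with an estimated correlation). In limma 0 genes passed, with 162 at an unadjusted p under 0.05, and 2 were lower after quantile normalization; without replicate 1 of wild type saline 2 passed.

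Between fosB-null and fosB d/d mice with saline, Prlhr, a receptor of prolactin-releasing peptide, was at -1.02 (SE 0.17, adjusted p = 0.172), Rprm at -0.60 (SE 0.11, adjusted p = 0.301) and Serpinb1a at 0.50 (SE 0.10, adjusted p = 0.301). By list, choroid plexus markers lay at -0.66 against all genes with 0 of 17 passing (adjusted p = 1.5e-07; adjusted p = 0.998 with an estimated correlation). That call was lost and its direction turned within set 2 (adjusted p = 0.989) and with array weights (adjusted p = 0.991); the score of replicate 1 of fosB-null saline was -1.36 against 0.80 and 0.84 in the other 2. In limma 0 genes passed, with 604 at an unadjusted p under 0.05; 2 were higher and 6 lower after quantile normalization, and 1 passed with the replicate number as a block. With quantile normalization the count was 71 with the replicate block, 278 with the array set block and 738 within set 2 (2 arrays per group).

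After KA, 7 of 27 late activity genes and 6 of 24 neuropeptide genes were lower in fosB-null than in wild type mice as deposited. List counts here include the shift of the median gene, -0.20, and of the 210 genes that passed 208 were lower. The changes of single genes below are relative to that median. Gal changed by -1.29 (SE 0.11, adjusted p = 2.3e-06), Nptx2 by -1.10 (SE 0.11, adjusted p = 7.9e-06), Thbs4 by -1.11 (SE 0.13), Penk by -1.03 (SE 0.17) and Trh by -1.64 (SE 0.40, adjusted p = 0.034). Lct, a marker of dentate granule cells in the lists used here, was higher by 0.97 (SE 0.18) and Dgkh, a diacylglycerol kinase, by 0.87 (SE 0.11). Trh was lost after quantile normalization (-1.67, adjusted p = 0.0651), as was Ccl12 (-1.19, SE 0.28, before it and -1.17, adjusted p = 0.0514, after).

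Of 27 late activity genes 7 were lower (13 adjusted over the list alone), with Vgf, a secreted neuropeptide precursor, at -0.51 (SE 0.10) and Gadd45b at -0.67 (SE 0.15). Of 24 neuropeptide genes 6 were lower (8 adjusted over the list alone). These lists gave adjusted p = 4.7e-05 and 5.2e-04 (adjusted p = 0.567 with an estimated correlation for each). Of 25 cytokines and chemokines 2 were lower (12 adjusted over the list alone), with Lif at -0.96 (SE 0.16), and of 31 reactive astrocyte genes 3 were lower (23 adjusted over the list alone). These gave adjusted p = 3.6e-05 and 1.5e-07 (adjusted p = 0.567 with an estimated correlation for each). Dentate granule markers were called up with 1 of 16 higher (2 adjusted over the list alone), and Dsp, a desmosome protein, stood at 0.82 (SE 0.19, adjusted p = 0.107) and Tdo2 at 0.82 (SE 0.23, adjusted p = 0.142); the list gave adjusted p = 2.4e-09 (adjusted p = 0.567 with an estimated correlation). Meningeal fibroblast markers, too, stood 0.36 above all genes, with 0 of 18 higher and 1 lower, also adjusted over the list alone, and Dcn, decorin, at 0.86 (SE 0.23, adjusted p = 0.127); the list gave adjusted p = 2.4e-09 (adjusted p = 0.567 with an estimated correlation).

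In limma 2 genes were higher and 208 lower, and 78 and 93 after quantile normalization, with 81 of 210 kept. With the array set as a block as well the count was 393. With array weights the list calls of reactive astrocyte (adjusted p = 0.297), neuropeptide (adjusted p = 0.136), late activity and cytokine genes (adjusted p = 0.0814 each) were lost. The count was 1991 with the replicate number as a block, 4253 without replicate 1 of wild type KA and 31 without replicate 3 of wild type KA.

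After KA, 15 of 31 reactive astrocyte genes and 10 of 25 cytokines and chemokines were lower in fosB d/d than in wild type mice as deposited. List counts here include the shift of the median gene, -0.22, and of the 394 genes that passed 391 were lower. The changes of single genes are likewise relative to that median. Timp1 changed by -1.83 (SE 0.32, adjusted p = 0.00358), Cd44 by -1.40 (SE 0.25, adjusted p = 0.00358), Gldn by -1.43 (SE 0.24) and Ptx3, a pentraxin, by -1.38 (SE 0.27). Etnppl was higher by 1.18 (SE 0.17) and Tsc22d3, a glucocorticoid-induced gene, by 0.71 (SE 0.12). Gal was lower as well, at -0.98 (SE 0.11, adjusted p = 3.9e-05), and Fos at -0.61 (SE 0.16, adjusted p = 0.0144). Ccl3, a chemokine, at -1.39 (SE 0.32), was lost after quantile normalization (-1.35, adjusted p = 0.105).

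Of 31 reactive astrocyte genes 15 were lower (23 adjusted over the list alone), with the median at -0.57 against all genes (adjusted p = 8.3e-15; adjusted p = 0.423 with an estimated correlation). Of 25 cytokines and chemokines 10 were lower (15 adjusted over the list alone), with Ccl12 at -1.27 (SE 0.28) and Lif at -1.05 (SE 0.16), and of 23 microglia markers 7 were lower (15 adjusted over the list alone), with Ly86 at -0.78 (SE 0.16) and Cd68 at -0.45 (SE 0.12). These lists gave adjusted p = 1.9e-08 and 1.7e-07 (adjusted p = 0.423 with an estimated correlation for each). Of 24 neuropeptide genes 6 were lower (adjusted over the list alone, 13 lower and 1 higher), with Npy at -0.50 (SE 0.15) and adjusted p = 1.3e-04 (adjusted p = 0.423 with an estimated correlation). Dentate granule markers were called up with 0 of 16 passing and 1 lower adjusted over the list alone, Lct being at 0.70 (SE 0.18, adjusted p = 0.108; list adjusted p = 8.7e-08; adjusted p = 0.423 with an estimated correlation). Choroid plexus markers stood 0.41 above all genes with 0 of 17 passing (adjusted p = 5.1e-10; adjusted p = 0.423 with an estimated correlation), and after quantile normalization adjusted p was 0.0513.

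In limma 3 genes were higher and 391 lower, and 48 and 87 after quantile normalization, with 88 of 394 kept. With array weights the list calls of reactive astrocyte (adjusted p = 0.708), neuropeptide (adjusted p = 0.108), cytokine (adjusted p = 0.104) and microglia genes (adjusted p = 0.068) were lost. The count was 61 without replicate 3 of fosB d/d KA and 5392 without replicate 1 of wild type KA.

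Between fosB-null and fosB d/d mice after KA, Rprm was at -0.61 (SE 0.11, adjusted p = 0.976), Smad3, a mediator of TGF-beta signalling, at -0.42 (SE 0.10, adjusted p = 1) and Necab3 at -0.51 (SE 0.13, adjusted p = 1). The reactive astrocyte list stood 0.20 above all genes in fosB-null against fosB d/d mice, with 0 of 31 passing, also adjusted over the list alone, and Timp1 at 0.87 (SE 0.32, adjusted p = 1; list adjusted p = 6.9e-10; adjusted p = 0.863 with an estimated correlation). With array weights the direction of that list turned (adjusted p = 0.388), and without replicate 1 of fosB d/d KA its call was lost (adjusted p = 0.0798). The late activity list stood at -0.11 with 0 of 27 passing, also adjusted over the list alone, Nptx2 being at -0.23 (list adjusted p = 1.4e-08; adjusted p = 0.863 with an estimated correlation). The choroid plexus list lay at -0.35 with 0 of 17 passing (adjusted p = 1.7e-05; adjusted p = 0.863 with an estimated correlation); within set 3 (2 arrays per group) 15 were lower adjusted over the list alone (adjusted p = 2.4e-21). In limma 0 genes passed, with 141 at an unadjusted p under 0.05, and 0 passed after quantile normalization.

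Ercc2, a DNA repair helicase whose gene lies near Fosb, was at -0.98 in fosB-null KA (SE 0.15, adjusted p = 0.00449) and -0.99 in fosB d/d KA (SE 0.15, adjusted p = 0.00295) against wild type, as deposited. Pglyrp1 was at -0.86 (SE 0.11, adjusted p = 0.00144) and -0.87 (SE 0.11, adjusted p = 0.00133), and Zfp180, a zinc finger gene chosen after its values were seen, at -0.76 (SE 0.13) and -0.72 (SE 0.13). Between the mutants Ercc2 was at -0.04 in saline and 0.01 in KA. Other neighbours, Kptn and Pnmal2, chosen after their values were seen, were higher after quantile normalization: 0.33 (adjusted p = 0.0141) and 0.54 (adjusted p = 0.00288) in fosB-null KA, and 0.29 (adjusted p = 0.0273) and 0.59 (adjusted p = 0.00179) in fosB d/d KA. Of 338 genes within 10 Mb of Fosb, 8 passed in fosB-null KA (2.37 percent, against 1.03 percent of other genes; Fisher's exact p = 0.0272) and 13 in fosB d/d KA (3.85 percent against 1.94; Fisher's exact p = 0.0263). In saline 1 passed in fosB-null mice, Vmn1r180, with 0 of the other genes (Fisher's exact p = 0.017), and 0 in fosB d/d. Any lone called gene near Fosb would give that p, so it rests on this gene alone. In the aged mice 4 passed in fosB-null without epilepsy (Fisher's exact p = 5.6e-04), 2 in fosB d/d (Fisher's exact p = 0.0142) and 0 in fosB-null with epilepsy. Adjusted over the 10 comparisons, Fisher's p was 0.00557 for fosB-null without epilepsy and 0.0544 for each of the other 4. After quantile normalization adjusted Fisher's exact p was 1.6e-06 for fosB-null and 9.6e-04 for fosB d/d with saline, 0.0178 and 0.133 after KA, 0.0178 without epilepsy and 3.6e-04 for aged fosB d/d. With quantile normalization and the array set as a block, Fisher's exact p was 9.5e-06 for fosB-null and 8.5e-04 for fosB d/d with saline, and 0.169 and 0.347 after KA.

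**Figure D3:**
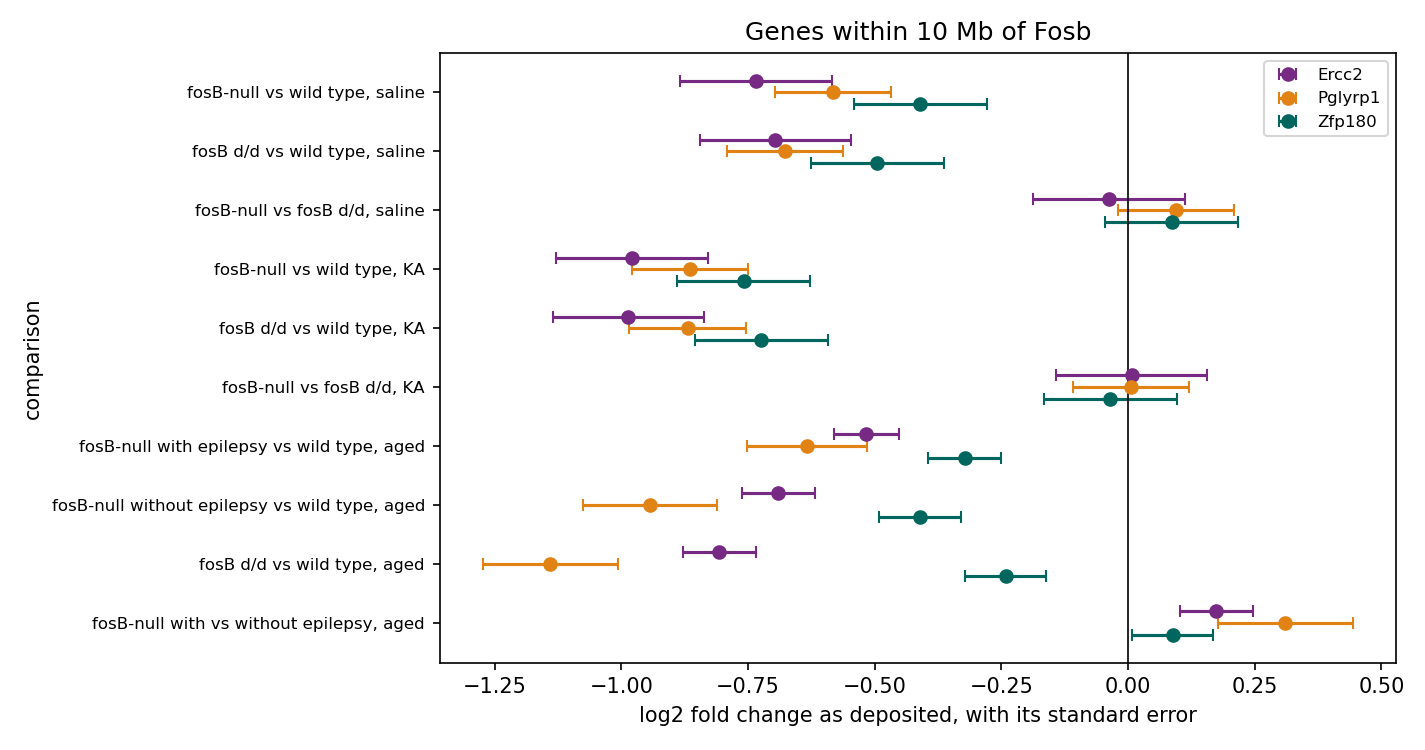
Log2 fold change of Ercc2, Pglyrp1 and Zfp180 as deposited, with its standard error, in 10 comparisons of genotypes. Ercc2 was at -0.73 in fosB-null and -0.70 in fosB d/d saline mice against wild type.

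In aged mice, fosB-null with epilepsy had no called gene against wild type. Car12, a carbonic anhydrase, was at 1.15 (SE 0.14, adjusted p = 0.145), Ercc2 at -0.52 (SE 0.06, adjusted p = 0.145) and Kptn at 0.50 (SE 0.08, adjusted p = 0.326), with 3 arrays each. Complement and MHC genes were called up with 0 of 18 passing and 3 higher adjusted over the list alone (median 0.15 above all genes, adjusted p = 1.6e-07; adjusted p = 0.317 with an estimated correlation). The reactive astrocyte list was called up with 0 of 31 passing, also adjusted over the list alone (median 0.16 above all genes, adjusted p = 3.0e-07; adjusted p = 0.511 with an estimated correlation). Beside these, choroid plexus markers stood 1.33 above all genes, with 0 of 17 passing and 14 higher adjusted over the list alone (adjusted p = 4.9e-23; adjusted p = 0.317 with an estimated correlation). Meningeal fibroblast markers stood 0.65 above, with 0 of 18 passing and 7 higher adjusted over the list alone (adjusted p = 2.2e-20; adjusted p = 0.317 with an estimated correlation). In limma 0 genes passed, with 616 at an unadjusted p under 0.05, and 51 passed without replicate 2 of fosB-null with epilepsy.

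**Figure D4:**
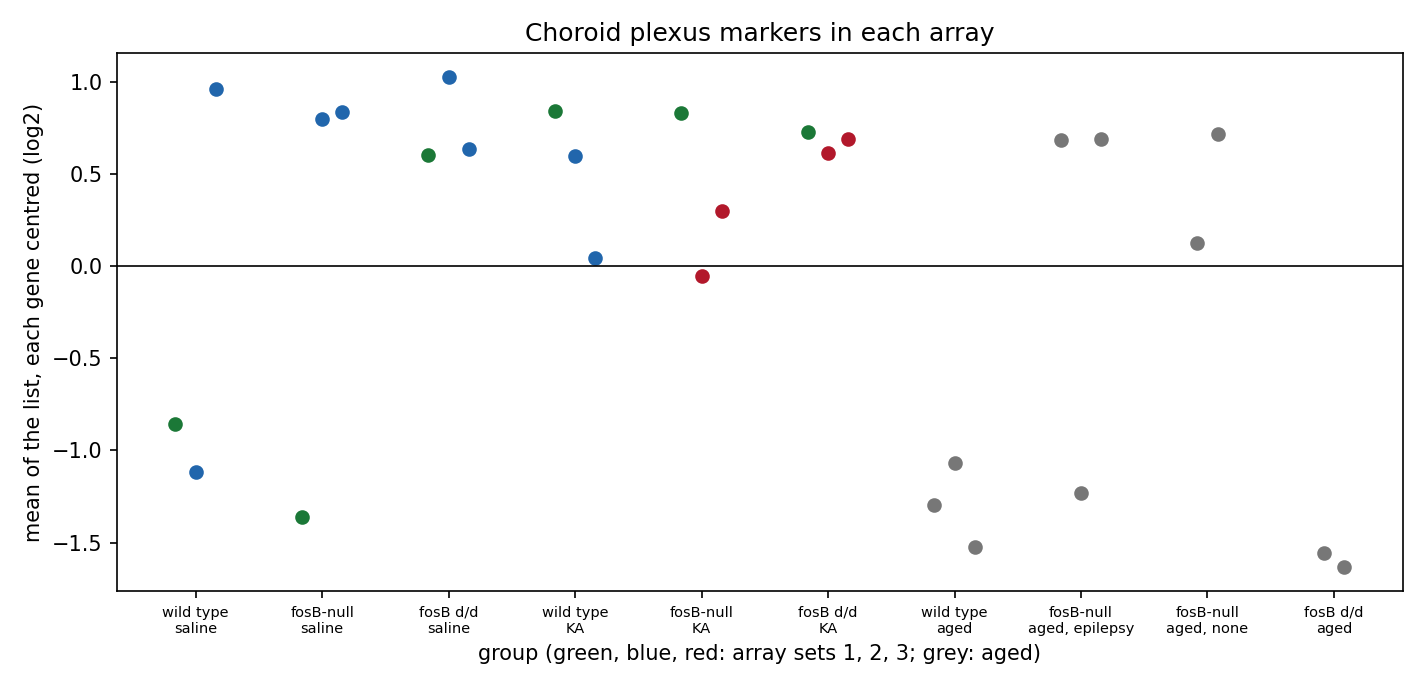
Mean of 17 choroid plexus markers in each array as deposited, each gene centred over the arrays, by group (1 point per array). Values were -1.30, -1.07 and -1.52 in aged wild type and 0.68, -1.23 and 0.69 in aged fosB-null with epilepsy.

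Aged fosB-null mice without epilepsy (2 arrays) differed from wild type by lower Cxcr2, a chemokine receptor, at -0.90 relative to the median gene, which moved by -0.14 (SE 0.12, adjusted p = 0.0305). Kbtbd6 (-0.82, SE 0.09), Pglyrp1 (-0.80, SE 0.13) and Ercc2 (-0.55, SE 0.07) were lower, and Cga, the glycoprotein hormone alpha subunit (1.14, SE 0.13), Lcn4 (0.90, SE 0.11) and Cd79a, a B cell receptor component (0.74, SE 0.08), were higher. Choroid plexus markers stood 2.03 above all genes, with 0 of 17 passing and 16 higher adjusted over the list alone (adjusted p = 6.5e-28; adjusted p = 0.795 with an estimated correlation), and meningeal markers 0.41 above, with 3 of 18 higher adjusted over the list alone and 0 among all genes (adjusted p = 2.2e-09; adjusted p = 0.795 with an estimated correlation). In limma 4 genes were higher and 19 lower, and 24 and 23 after quantile normalization, with 13 kept; Pglyrp1 was lost (-0.82, adjusted p = 0.0526). Leaving out any 1 of the 5 compared arrays took the count to 0.

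Aged fosB d/d mice (2 arrays) had lower Pglyrp1 (-1.01 relative to the median gene, which moved by -0.13; SE 0.13, adjusted p = 0.0406), Cxcr2 (-0.91, SE 0.12), Ercc2 (-0.67, SE 0.07) and Pcbd2 (-0.63, SE 0.10) than wild type, and higher Lcn4 (0.97, SE 0.11). Circadian clock genes were called down with 0 of 16 passing and 6 lower adjusted over the list alone, Dbp at -0.33 relative to the median gene (adjusted p = 0.00965; adjusted p = 0.491 with an estimated correlation). That call was lost with age as a covariate (adjusted p = 0.0848). In limma 1 gene was higher and 10 lower, and 19 and 23 after quantile normalization, with 6 kept; leaving out any 1 of the 5 compared arrays took the count to 0.

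Between aged fosB-null mice with and without epilepsy (3 and 2 arrays), Cxcr2 was higher by 0.75 (SE 0.12), Pcbd2 by 0.70 (SE 0.10) and Kbtbd6 by 0.65 (SE 0.09) with epilepsy, relative to the median gene, which moved by 0.15, each with adjusted p = 0.0451. Cga was lower (-1.11, SE 0.13), as was Cd79a (-0.74, SE 0.08). The choroid plexus list lay at -0.59 against all genes with 0 of 17 passing (adjusted p = 1.1e-07; adjusted p = 0.995 with an estimated correlation). Without replicate 2 of fosB-null with epilepsy, whose score was -1.23 against 0.68 and 0.69 in the other 2, the direction turned (adjusted p = 0.936). In limma 10 genes were higher and 2 lower, and 15 and 18 after quantile normalization, with 4 kept; Kbtbd6 was lost (0.64, adjusted p = 0.11). The count was 0 without replicate 2 and 1422 without replicate 1 of fosB-null with epilepsy.

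Aged wild type mice differed from those of 10 weeks most in sex-linked genes. Xist, the RNA of the inactive X chromosome, was higher by 5.37 relative to the median gene, which moved by -0.17 (SE 0.50), and the Y-linked genes Eif2s3y (-5.70, SE 0.18), Uty (-4.06, SE 0.14) and Kdm5d (-3.20, SE 0.16) were lower, although all mice are labelled female. Age and this difference go together. So do age and the injection, saline in the young and none named in the aged mice, and any array batch, which the labels do not give. No value of this comparison therefore belongs to age alone. C4b, a complement component, was higher by 1.41 (SE 0.23, adjusted p = 0.0207) and Pcdhb3, a protocadherin, by 0.91 (SE 0.11, adjusted p = 0.00265). Tnc (-0.73, SE 0.14, adjusted p = 0.00412) and Cldn5, a tight junction protein of endothelium (-0.54, SE 0.14), were lower, and both were lost after quantile normalization (-0.68, adjusted p = 0.128, and -0.54, adjusted p = 0.195).

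Microglia markers were called up with 0 of 23 passing and 1 higher adjusted over the list alone, Ctss, a cathepsin, being at 0.57 relative to the median gene (SE 0.11, adjusted p = 0.132; list adjusted p = 5.4e-11; adjusted p = 0.371 with an estimated correlation). Immediate early genes were called up with 0 of 32 passing, also adjusted over the list alone, Npas4 at 1.06 (SE 0.37) among them (adjusted p = 3.9e-11; adjusted p = 0.437 with an estimated correlation). Glucocorticoid response genes had 0 of 17 passing, also adjusted over the list alone, with Tsc22d3 at 0.46 (SE 0.14), and were called up (adjusted p = 3.2e-09; adjusted p = 0.371 with an estimated correlation). Proliferation genes were called down with 0 of 26 passing and 13 lower adjusted over the list alone, Ccna2, a cyclin, being at -0.34 (SE 0.11; list adjusted p = 1.9e-05; adjusted p = 0.437 with an estimated correlation). Meningeal fibroblast markers stood at -0.58 against all genes, with 0 of 18 passing and 10 lower adjusted over the list alone (adjusted p = 8.0e-06; adjusted p = 0.494 with an estimated correlation). In limma 3 genes were higher and 19 lower, and 17 and 9 after quantile normalization, with 11 of 22 kept. The count was 4 without replicate 2 of aged wild type and 2033 without replicate 1 of wild type saline.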

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

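The tests of scale, array set and sex labels in this part were chosen after the result was seen; the test near Fosb and the splits were chosen before the data were examined.

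A difference between groups in the KA response, by the interaction test, marks the following as deposited. In fosB-null against wild type mice the differences were Gal -1.87, Nptx2 -1.39, Thbs4 -1.41, Klk1b8 -1.37, Bcl2a1c -1.30, Pate13 -1.31, Cst7 -1.14 and Vmn1r180 1.52. In fosB d/d mice they were Thbs4 -1.71, Gal -1.24 and Nptx2 -1.18. A signal that no comparison was designed for marks Eif2s3y, a Y-linked gene, at -5.86 in aged against young wild type mice.

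The differing KA response of these genes was weighed against the deposited scale and an additive difference between array sets. After quantile normalization 6 of 8 genes in fosB-null and 2 of 3 in fosB d/d mice passed, and with the array set as a block 7 and 3 passed. This speaks against either as the sole source. Vmn1r180, with its positive difference among the 6, lies within 10 Mb of Fosb and was lower in fosB-null saline mice. Its difference is thus not parted from those near the targeted locus. Of 100 relabellings of genotype, 13 and 9 gave as many genes, the highest count being 4760 and 5359; these relabellings mix the array sets, so they do not settle whether chance gives such counts. That block removes additive set differences gene by gene, with replicate 1 alone tying the mutants after KA to the other groups; set differences that depend on treatment were not tested. The biological explanation, an effect of the altered fosB gene on the response, with Thbs4 higher in wild type and lower in the mutants after KA, was tested by the interaction alone.

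Near Fosb, Ercc2 and Pglyrp1 were lower than in wild type, while Kptn and Pnmal2 were higher after quantile normalization (0.33 and 0.54 in fosB-null KA). The explanation set against an effect of Fosb, strain sequence around the targeted locus, was tested by Fisher's exact test on genes within 10 Mb. Its p was under 0.05 in 5 of the 5 comparisons of a mutant with wild type that had any called gene (1 gene, Vmn1r180, in fosB-null saline). Adjusted over the 10 comparisons, p was 0.00557 for aged fosB-null mice without epilepsy and 0.0544 for the other 4 of these. Between fosB-null mice with and without epilepsy, Fisher's exact p was 0.186. After quantile normalization adjusted Fisher's exact p was 1.6e-06 for fosB-null saline, 9.6e-04 for fosB d/d saline, 0.0178 and 0.133 for these after KA, 0.0178 without epilepsy and 3.6e-04 for aged fosB d/d. At the unadjusted threshold Fisher's exact p was 3.5e-07 and 4.1e-06 for fosB-null and fosB d/d saline, 0.00178 and 0.0591 after KA, 7.0e-06 with and 0.103 without epilepsy and 0.21 for aged fosB d/d. At the adjusted threshold, with quantile normalization and the array set block, Fisher's exact p was 9.5e-06 and 8.5e-04 in saline, 0.169 and 0.347 after KA. Strain sequence fits the values under 0.05 against wild type, but a regional effect of the altered locus, which was not tested, is not parted from it. Fosb-null mice with and without epilepsy share the genotype label. At the unadjusted threshold Fisher's exact p between them was 0.168, and 6.0e-04 after quantile normalization (17.2 percent near Fosb against 10.9). A difference in the labelled genotype does not account for that last value. Whether the sequence around the locus differs between these mice was not tested.

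The Y-linked signal of the young arrays was weighed against sex labels and scale. In 18 of 18 young arrays Eif2s3y, Kdm5d and Uty lay above, and Xist below, every aged array, which fits male young mice. After quantile normalization Eif2s3y was at -5.62, far beyond the largest gap between array medians, 0.477, so scale is not the source. Xist was at 9.55 in replicate 1 of wild type saline and 7.58 in replicate 3 of fosB d/d saline against 5.81 to 6.67 in the other young arrays. No biological explanation was tested.

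For the other counts only 10 splits of 3 against 3 arrays exist, too few to exclude chance. Splits with at least the real count, with the real count and the highest other, were for KA 1 (510 and 1) in wild type, 1 (15 and 0) in fosB-null and 1 (6 and 0) in fosB d/d mice. Against wild type after KA they were 1 (210 and 0) for fosB-null and 2 (394 and 1000) for fosB d/d, and 2 (1 and 241) for fosB-null with saline. They were 10 (0 and 0) for fosB d/d against wild type and for fosB-null against fosB d/d with saline, 10 (0 and 12) for the latter after KA, 10 (0 and 1) for epilepsy in aged mice and 1 (22 and 0) for age. The splits with 1000 and 241 genes point to structure among the arrays.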

How the results depend on the processing

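Quantile normalization with a block and the fits within 1 array set were chosen after the result was seen. Abbreviated, KA-wt, KA-null and KA-dd are KA against saline; int-null and int-dd the interactions. Main counts were KA-wt 510, KA-null 15, KA-dd 6, int-null 8, int-dd 3; against wild type, null-saline 1, dd-saline 0, null-KA 210, dd-KA 394; null against dd 0 in saline and in KA; aged epilepsy 0, no epilepsy 23, dd 11; epilepsy against none 12; age 22.

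Quantile normalization gave KA-wt 1427, KA-null 139, KA-dd 85, int-null 37, null-saline 16, dd-saline 2, null against dd saline 8, dd-KA 135, no epilepsy 47, dd aged 42, epilepsy against none 33. The replicate block gave KA-wt 1139, KA-null 134, KA-dd 475, int-null 471, int-dd 66, null-saline 11, null against dd saline 1, null-KA 1991, dd-KA 4021, no epilepsy 0, dd aged 0, epilepsy against none 0, age 67; the block changed no other call where the numbers pair. Elsewhere same-numbered correlations were -0.32 to 0.17 for KA-wt, -0.14 to 0.57 for dd-KA and 0.07 to 0.52 for age. They were -0.002 to 0.52 for null-saline and 0.002 to 0.69 for null against dd KA. The numbers were thus not taken as pairs there, although number 1 marks array set 1 in the young groups. In each, 1 of 3 arrays correlated best with its own number, or 2 of 3 for null-saline. KA-null, where the numbers were taken to pair, also had 1 of 3. Quantile normalization with the replicate block gave KA-wt 2911, KA-null 485, KA-dd 483, int-null 488, int-dd 30, null-saline 111, dd-saline 3, null against dd saline 71, null-KA 728, no epilepsy 0, dd aged 1, epilepsy against none 2, age 48; with the array set block KA-wt 3634, KA-dd 36, int-null 243, int-dd 160, null-saline 319, dd-saline 3, null against dd 278 in saline and 4 in KA, null-KA 393. Within 1 set counts were KA-wt 3632, null-saline 1233, dd-saline 1, null against dd saline 738.

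Array weights gave KA-wt 3460, KA-null 13778, KA-dd 15355, int-null 8545, int-dd 8644, null-saline 1484, dd-saline 4, null against dd 5606 in saline and 499 in KA, null-KA 12853, dd-KA 13835, epilepsy 451, no epilepsy 4844, dd aged 1147, epilepsy against none 7597, age 7700. All 28 arrays in 1 fit gave KA-null 141, KA-dd 128, int-null 139, int-dd 18, null-saline 6, null against dd saline 2, null-KA 997, dd-KA 1891, dd aged 7, epilepsy against none 22. Only the compared groups gave KA-wt 173, KA-null 2, KA-dd 95, int-null 5, null-saline 0, null-KA 8, dd-KA 65, no epilepsy 44, dd aged 0, epilepsy against none 0, age 3. Without the dimmest 30 percent counts were KA-null 39, KA-dd 10, int-null 2, null-saline 0, epilepsy 2, no epilepsy 8, dd aged 7, epilepsy against none 4. Trended and robust moderation gave KA-null 45, KA-dd 10, int-null 4, int-dd 5, null-saline 0, epilepsy 1, dd aged 5, epilepsy against none 2. The age covariate gave no epilepsy 0, dd aged 0, epilepsy against none 0. With the mean of probe sets 16 of 16 counts lay within 1.5 times the main one, with KA-wt 508, int-null 7, null-KA 192 and dd-KA 397. In the settings above, counts within that bound are not printed. The cause was not tested.

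Leaving out 1 array gave ranges of KA-wt 255 to 622, KA-null 3 to 119, KA-dd 2 to 118, int-null 4 to 1521, int-dd 3 to 18, null-saline 0 to 5, dd-saline 0 to 2, null against dd 0 to 0 in saline and in KA, null-KA 31 to 4253, dd-KA 61 to 5392, epilepsy 0 to 51, no epilepsy 0 to 0, dd aged 0 to 0, epilepsy against none 0 to 1422, age 4 to 2033. A lone array left in a group was assumed to vary like the others.

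The choroid plexus list of null against dd saline turned with array weights (adjusted p = 0.991) and within set 2 (0.989), the reactive astrocyte list of null against dd KA with array weights (0.388), and the choroid plexus list of epilepsy against none without replicate 2 of the epilepsy group (adjusted p 3.4e-13 to 0.936 over arrays left out). Quantile normalization kept 167 of 212 named genes and 69 of 72 lists; an estimated correlation lost 70 of 72 lists; arrays left out kept 481 of 494 list results. Of 10 comparisons of genes near Fosb, 2 were weaker at 2 Mb and 3 at 30 Mb, and with the unadjusted threshold 3 were weaker and 2 stronger. The score cannot pass, as its smallest exact permutation p is 0.1. With 100 genes per direction, quantile-normalized values or both its difference after KA was -0.13 to -0.19 in fosB-null (exact permutation p 0.2 to 0.6) and -0.45 to -0.53 in fosB d/d mice (0.1 to 0.2). Saline was not subtracted. After quantile normalization the saline score was -0.34 in fosB-null and -0.59 in wild type mice, so these differences are not differences of the response. Signal over background was not analysed here.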

Other observations

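The list tests here were fixed before the data were examined; the values of single arrays were chosen after the result was seen. The KA response of circadian clock genes was called higher in fosB d/d than in wild type mice by the list test, with 0 of 16 passing, also adjusted over the list alone (median 0.36 above all genes, adjusted p = 6.9e-08; adjusted p = 0.566 with an estimated correlation). Against all genes the list median after KA was -0.14 in wild type and 0.13 in fosB d/d mice. Dbp, an output gene of the clock, was at 0.81 (SE 0.28) and Ciart, a clock repressor, at 0.78 (SE 0.30) relative to the median gene. Cholesterol synthesis genes were called up likewise in each mutant, with 0 of 18 passing, also adjusted over the list alone, and medians 0.27 (fosB-null, adjusted p = 2.6e-05) and 0.29 (fosB d/d, adjusted p = 6.9e-08) above all genes. With an estimated correlation these gave adjusted p = 0.697 and adjusted p = 0.501. Insig1, a regulator of the pathway, was at 0.58 (SE 0.21) and 0.65 (SE 0.21). With saline, the clock list was already called down in fosB d/d against wild type mice (Ciart at -0.85), and the cholesterol list in fosB-null mice. There the interaction does not tell a larger rise after KA from a lower saline level.

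In replicate 1, whose 6 young arrays form 1 set, the KA differences after quantile normalization (1 array each, no test) were as follows. Gal was at 1.75 in wild type, 0.09 in fosB-null and 0.81 in fosB d/d mice, Nptx2 at 1.10, -0.16 and -0.03, and Thbs4 at 0.55, -0.88 and -1.14. Timp1 was at 4.89, 2.79 and 2.20, and Gfap at 1.53, 1.04 and 0.94.

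Replicate 2 of aged fosB-null with epilepsy had the highest aged value of several activity genes: Fos at 9.63 (7.87 to 8.74 in the 9 other aged arrays), Npas4 at 11.51 (8.96 to 10.31), Nptx2 at 11.78 (9.22 to 10.01) and Bdnf at 9.30 (7.99 to 8.38). The same array had Fosb at 9.64, against 8.23 and 8.64 in the other 2 of its group, and the lowest choroid plexus score of that group (-1.23).

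Choroid plexus scores varied within groups, from -1.12 to 0.96 in wild type saline and from -1.36 to 0.84 in fosB-null saline. Ttr, a choroid plexus transcript, was at 13.11 ± 0.91 in wild type saline, 14.03 ± 0.04 in fosB d/d saline and 10.78 ± 0.40 in aged fosB d/d mice.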
